A study of Homo sapiens with 9 samples.

How the data were processed

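RNA-seq libraries from 9 cultures or aliquots of MDA-MB-468 cells were compared, 3 with the control hairpin shNC, 3 with shFAM83H-AS1_1 and 3 with shFAM83H-AS1_2. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures, so they may be technical replicates. The authors supplied FPKM values per gene, that is, reads scaled by the length of the gene model and by the depth of the library. Their notes name HISAT2 2.1.0, Bowtie2 2.2.3, HTSeq 0.6.0 and hg38 without saying what each was used for. The strand setting and the annotation release are not given in the sources used here. The table held 31005 lines, of which 1 was a stray fragment of text and was left out, leaving 31004 genes. Gene symbols came from a gene name table for 30883 identifiers and from GENCODE release 29 alone for 107. The target FAM83H-AS1 was found by its identifier, which the gene name table lists as IQANK1 with FAM83H-AS1 as a synonym. The hairpin sequences are not in the labels, so whether they match this gene model, and which of its transcripts, was not checked.

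FPKM values of genes with few reads are whole multiples of the value of 1 read, which gave the number of reads behind each value. Whole reads were recovered for 100% of the 31004 genes within a tolerance of 1e-05 reads, and the same steps recovered 100% of 3928 genes in simulated data. The depths by which the FPKM were scaled correspond to 15270673 to 18115070 reads per library. Reads entered 1 alternative, the gene lengths used for length trends and medians, and the read numbers given for libraries and single genes. They also entered the chi-square values below and the simulated data that show which changes the test finds. Pooled over 14250 to 14926 genes per pair of replicates, chi-square per degree of freedom was 13.72 or more, where pure counting error would give about 1. Genes with many reads weigh most in this value. For how many genes the spread between libraries exceeds counting error was not measured. Short genes can hold few reads at 1 FPKM, and for these counting error is large.

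Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per group, all 9 libraries in 1 fit, and moderated variances that follow the mean level. Genes with at least 1 FPKM in at least 3 of the 9 libraries were kept, which left 11875. The 3 contrasts were each hairpin against shNC and shFAM83H-AS1_2 against shFAM83H-AS1_1. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 11875 genes, with 0.05 as threshold. On simulated data with the spread of these libraries, the test found 12.1%, 34.3% and 89.6% of genes changed 1.5-fold, 2-fold and 4-fold with shFAM83H-AS1_1, and 13.6%, 35.8% and 91% with shFAM83H-AS1_2, with 6 false calls in each comparison. Of 30 gene lists, the 27 with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The mitochondrially encoded, cytosolic ribosomal protein and histone lists also served as checks of RNA quality. The level of the target was also compared by exact permutation tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and drew the plots.

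The groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the target and the measured genes of its locus. It names up to 10 genes on each side changed by both hairpins, and for each contrast the 5 genes with the highest and the 5 with the lowest log2 change among those past the threshold without overlap between groups and with a mean of at least 1 FPKM in a group. From each list it names the 4 members with the smallest p for the mean effect of both hairpins. Genes with clone-like or LINC symbols are counted but not named by the rule. The alternatives were another pseudocount (0.1), no filter and a stricter one (5 FPKM), 3 scalings between libraries, a replicate block, fits of only the 2 groups compared, a robust variance model, a minimum log2 change of 1, and leaving out each library in turn. Removal of trends with GC content, library weights, voom on the recovered reads, removal of GC trends together with 1 library or the block, and the block in fits of only the 2 groups were added after seeing the data. Deviations from the group means correlated at 0.20, 0.35 and 0.39 between same-numbered libraries of shNC and shFAM83H-AS1_2, each above 0.1, so the numbers were taken to pair these groups, although the labels name no shared batch. The pairs were read from the same values that the paired fits test, so the results of those fits are partly set by this choice. Trends with GC content ran in the same replicate order in both groups. Their Spearman correlations in replicates 1, 2 and 3 were -0.41, -0.04 and -0.60 in shNC and -0.14, 0.57 and -0.37 in shFAM83H-AS1_2. Whether these trends make the pairs was not tested. With shFAM83H-AS1_1 the numbers did not pair the libraries (-0.45 to 0.18). Agreement between the hairpins was set against 100 simulated data sets in which the groups share only the control libraries. Genes were drawn independently of each other there, so the SDs over these sets leave out that genes move together.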

Results

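MDA-MB-468 is a basal-like, triple-negative breast cancer line. Cells were transduced at an MOI of 10 with lentivirus carrying a control hairpin (shNC) or 1 of 2 hairpins against the long noncoding RNA FAM83H-AS1 and were selected with puromycin at 1 µg/mL. Libraries were made from 2 µg of total RNA. There were 3 groups of 3 libraries, with 15264204 to 18106105 gene reads per library, and 10665 to 11807 genes reached 1 FPKM. Replicates correlated at 0.979 to 0.988 across genes on the log2 scale, except that shFAM83H-AS1_1 replicate 3 correlated at 0.950 and 0.941 with its replicates. This library had a score of 61.2 on the first principal component, which held 53.5% of the variance, while the other 8 lay between -24.3 and 5.7. It had the fewest genes at 1 FPKM or more (10665), at a depth of 15993972 gene reads.

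**Figure D1:**
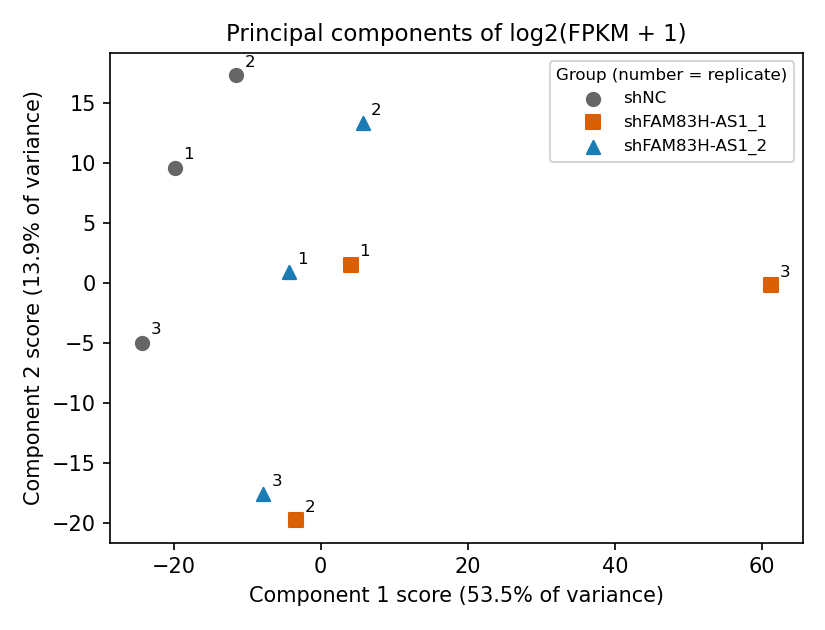
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), without units, coloured by group and numbered by replicate. Replicate 3 of shFAM83H-AS1_1 lies at 61.2 on the first component and the other 8 libraries between -24.3 and 5.7.

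The first question was how far each hairpin lowered its target. FAM83H-AS1 (IQANK1, ENSG00000203499, hg38 chromosome 8, 143734140 to 143790644, plus strand) had 16.5 ± 1.98 FPKM in control cells (SD, n = 3). With shFAM83H-AS1_1 it fell to 5.95 ± 1.27 FPKM (SD, n = 3), 35.9% of control, with a log2 change of -1.35 (SE 0.15, limma adjusted p = 0.00637), lower in 3 of 3 libraries. With shFAM83H-AS1_2 it was 7.98 ± 0.551 FPKM (SD, n = 3), 48.2% of control and lower in 3 of 3 libraries, with a log2 change of -0.96 (SE 0.15) that missed the threshold over all genes (limma adjusted p = 0.142). Its exact two-sided permutation p was 0.1 with each hairpin, the smallest that 3 against 3 libraries allow. The call with shFAM83H-AS1_2 depended on the library that stands apart, since the adjusted p was 0.018 without shFAM83H-AS1_1 replicate 3. It was 0.00503 in a fit of only shNC and shFAM83H-AS1_2 with same-numbered libraries as pairs, and over the 25 alternatives it ranged from 0.000637 to 0.597. The adjusted p with shFAM83H-AS1_1 ranged from 0.000353 to 0.161 over its 25 alternatives. The difference between the hairpins, 0.38 on the log2 scale, did not pass the test (limma adjusted p = 0.593; 0.32 to 0.946 over the alternatives).

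FAM83H, the protein-coding gene on the opposite strand, overlaps the target by 4095 bp and had 48.0 ± 7.71 FPKM in control cells, 44.5 ± 6.42 with shFAM83H-AS1_1 and 50 ± 5.73 with shFAM83H-AS1_2 (SD, n = 3 each). Its log2 changes were -0.10 and 0.06, and neither passed the test (limma adjusted p = 0.669 and 0.953). Because the strand setting is unknown, reads in the overlap may be counted for either gene. Among the 16 measured genes of the locus at 8q24.3, the target alone passed the test, with shFAM83H-AS1_1. The other 15 had log2 changes between -0.25 (GFUS) and 0.33 (GRINA) with shFAM83H-AS1_1, and between -0.07 (EPPK1) and 0.19 (GSDMD) with shFAM83H-AS1_2. GSDMD, PARP10, PLEC, SCRIB, PUF60, EEF1D, PYCR3, TIGD5, ZNF707, ZNF623 and NRBP2 were measured and did not pass with either hairpin. As a list that includes the target, the locus did not pass camera (adjusted p = 0.633 and 0.857). With shFAM83H-AS1_1 it passed as lower with GC trends removed (0.00829), also without shFAM83H-AS1_1 replicate 3 (0.0109) or with the replicate block (0.00698), and ranged from 0.00698 to 0.907 over the alternatives. These used the preset correlation. With an estimated one, on the values without removal of trends, the camera adjusted p was 0.87. Adjusted over the list alone, the target passed with both hairpins.

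**Figure D2:**
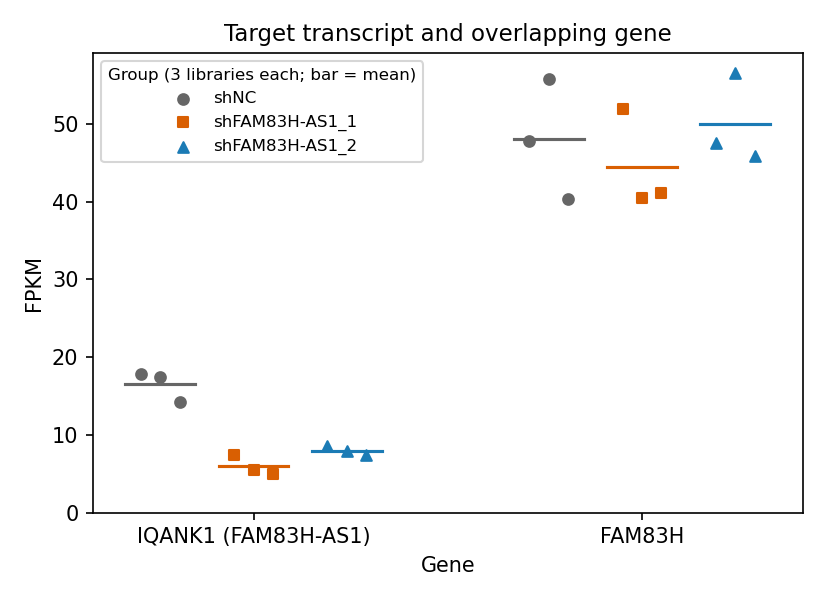
FPKM of FAM83H-AS1 (listed as IQANK1) and of the overlapping gene FAM83H in each library of the 3 groups, with points for libraries and bars for group means. All 6 knockdown libraries lie below the 3 control libraries for the target, whose group means were 16.5, 5.95 and 7.98 FPKM, while the groups overlap for FAM83H.

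With shFAM83H-AS1_1, transcripts for secreted inflammatory proteins were much lower than in control cells, and those of a basal keratin and an apoptosis ligand were higher. CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203), a chemokine that attracts monocytes, fell from 20.7 ± 1.38 to 1.68 ± 1.28 FPKM (SD, n = 3 each), a log2 change of -3.14 (SE 0.32, limma adjusted p = 0.00314). CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871308), a neutrophil chemokine, fell from 17.8 to 1.30 FPKM (log2 change -3.13, SE 0.28, limma adjusted p = 0.00175). CXCL8, which encodes interleukin-8, fell from 8.92 to 0.791 FPKM (-2.56), and TNF, the cytokine tumour necrosis factor, from 11.5 to 1.35 FPKM (-2.39), each with a limma adjusted p of 0.00314. ID4, an inhibitor of helix-loop-helix transcription factors, fell from 5.68 to 0.515 FPKM (-2.06, limma adjusted p = 0.0169). Each of these 5 genes was lower in 3 of 3 libraries than in every control library.

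Of the named genes past the threshold, TNFSF10, the death ligand TRAIL, had the highest log2 change, 1.90 (SE 0.27, limma adjusted p = 0.0173). It rose from 0.689 ± 0.148 to 5.60 ± 2.40 FPKM (SD, n = 3 each). KRT5 (ENSG00000186081, chromosome 12, 52514575 to 52520530), a keratin of basal epithelial cells, rose from 40 ± 8.52 to 128 ± 37.7 FPKM (1.63, SE 0.22, limma adjusted p = 0.0158). DIRAS3, an imprinted gene for a Ras-like GTPase, rose from 2.68 to 10.7 FPKM (1.68, limma adjusted p = 0.011). MALL rose from 0.587 to 5.01 FPKM (1.77, limma adjusted p = 0.0444), and the noncoding RNA PCAT6 rose from 1.85 to 8.21 FPKM (1.66, limma adjusted p = 0.0286). Log2 changes are of FPKM + 1, which makes those of genes near or under 1 FPKM smaller. Over the alternatives, which include a pseudocount of 0.1, the log2 change ranged from 1.42 to 2.94 for TNFSF10, 1.27 to 2.88 for MALL and -4.48 to -1.75 for CXCL3. Of 11875 genes, 187 passed the threshold, 111 higher and 76 lower, and 3005 had an unadjusted p under 0.05. The genes called higher were rich in GC and short, with medians of 58.6% GC and 2620 bp. Those called lower had 50.8% and 3440 bp, and all tested genes 50.2% and 4620 bp. In 3522 genes (29.7%) the 3 libraries of shFAM83H-AS1_1 did not overlap with the 3 controls, where chance gives 10% on average over groupings. Genes move together, so 1 grouping can depart from this average by chance, and how far was not counted. The number of calls moved with single libraries: it was 14, 31 and 9 without shNC replicates 1, 2 and 3, 59 and 1008 without shFAM83H-AS1_1 replicates 1 and 2, and 49, 42 and 64 without shFAM83H-AS1_2 replicates 1, 2 and 3. Without shFAM83H-AS1_1 replicate 3 it was 209. The 9 genes called in each of these 9 fits were CCL2, CXCL1, CXCL3, CXCL8, TNF, ICAM1, UTP18, PRPF38A and the target, chosen for mention after their values were seen. TNFSF10 lost its call when any 1 of the 3 controls was left out (adjusted p up to 0.0805), KRT5 without shNC replicate 2 or 3 (up to 0.0716), DIRAS3 without shNC replicate 3 (0.0554) and ID4 without shNC replicate 1 or 3 (up to 0.094). PCAT6 lost it when any 1 control or shFAM83H-AS1_2 replicate 2 was left out (up to 0.137), and MALL kept it only without shFAM83H-AS1_1 replicate 2 or 3 (up to 0.167 in the other fits).

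**Figure D3:**
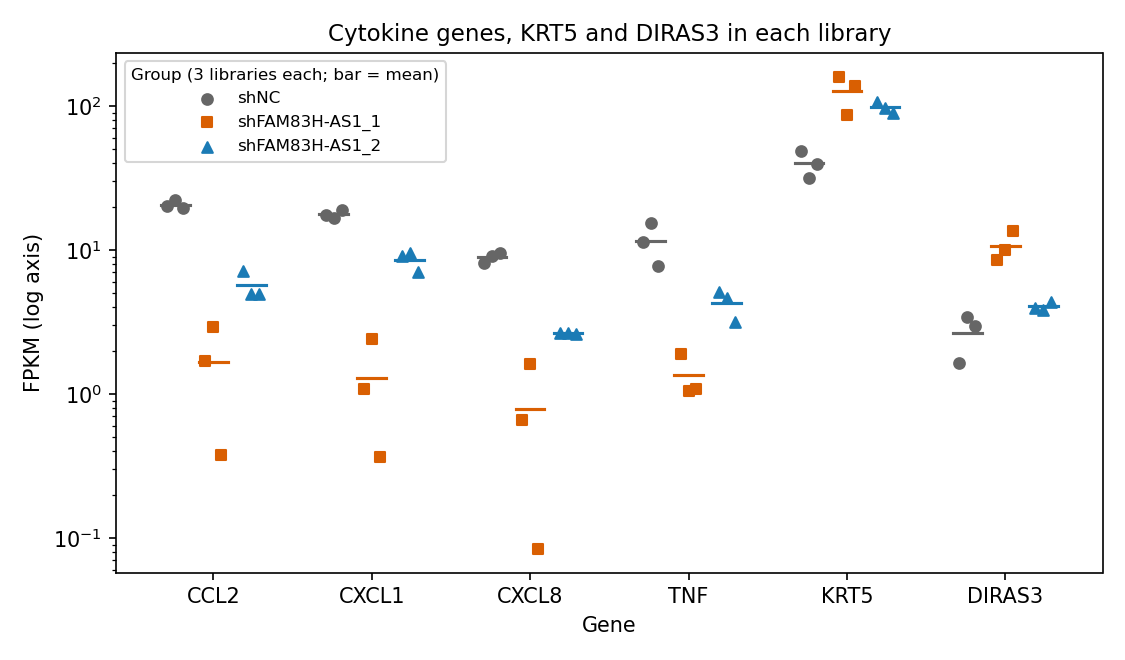
FPKM on a log axis of 4 cytokine genes, KRT5 and DIRAS3 in each library, with points for the 3 libraries of each group and bars for group means. For CCL2, group means were 20.7 (shNC), 1.68 (shFAM83H-AS1_1) and 5.70 FPKM (shFAM83H-AS1_2), and for KRT5 they were 40, 128 and 98.2 FPKM.

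NF-kB targets and inflammatory cytokines formed the list with the lowest median with shFAM83H-AS1_1, -1.27 on the log2 scale. All 19 measured members had a negative log2 change, 13 passed the test over all genes, and 17 passed adjusted over the list alone. Besides the chemokines above, CXCL3 fell from 3.35 to 0.161 FPKM (-1.91, limma adjusted p = 0.00175), ICAM1, an adhesion molecule for leukocytes, fell from 33.1 to 11.5 FPKM (-1.46, limma adjusted p = 0.00175), and NFKBIA, the inhibitor that NF-kB itself induces, fell by 0.57 on the log2 scale, a call kept only without shFAM83H-AS1_1 replicate 2 or 3 (adjusted p up to 0.137 in the other fits). The list passed camera (adjusted p = 5.04e-16) and fry (adjusted p = 0.00228). It did not pass camera with an estimated correlation (adjusted p = 0.39 with an estimated correlation). Its mean per library was -1.14, -1.29 and -1.70 relative to the control mean in replicates 1, 2 and 3 of shFAM83H-AS1_1.

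Of the other lists, 3 passed camera as lower with shFAM83H-AS1_1. MYC and ribosome biogenesis genes fell, with a median of -0.67 and 30 of 31 members negative; 0 passed limma over all genes, where 3005 genes had an unadjusted p under 0.05, and 21 passed adjusted over the list alone. Examples are the nucleolar proteins NOP56 (51.1 and 30.4 FPKM, -0.76) and NOLC1 (77.6 and 41.7 FPKM, -0.98), the polyamine enzyme ODC1 (118 and 67.4 FPKM, -0.87) and WDR12 (7.19 and 5.34 FPKM, -0.38). The camera adjusted p was 8.9e-08 (adjusted p = 0.56 with an estimated correlation). YAP/TEAD targets fell, with a median of -0.46, 12 of 15 members negative, 0 called over all genes and 3 adjusted over the list alone; AMOTL2 had -0.87, TGFB2 -1.04, CRIM1 -0.54 and CCN2 -1.34. Their camera adjusted p was 0.0148 (adjusted p = 0.56 with an estimated correlation). It was 0.00103 to 0.0776 over the alternatives, past the threshold in 23 of 24. Genes of DNA repair by homologous recombination fell, with a median of -0.35, 21 of 21 members negative and 0 called, over all genes or adjusted over the list alone; RAD54L had -0.48, FANCD2 -0.41, RAD51C -0.39 and FANCB -0.41. Their camera adjusted p was 0.0122 (adjusted p = 0.631 with an estimated correlation); it was 0.345 without shFAM83H-AS1_1 replicate 3, and 0.000195 to 0.831 over the alternatives. Replicate 3 of shFAM83H-AS1_1 carried much of these 3 shifts: relative to the control mean, the list means in replicates 1, 2 and 3 were -0.25, -0.46 and -1.22 for MYC and ribosome biogenesis, -0.21, -0.28 and -0.84 for YAP/TEAD targets, and -0.08, -0.04 and -0.88 for homologous recombination. With GC and length trends removed, the means for homologous recombination were 0.07, -0.04 and -0.49.

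The lists that rose with shFAM83H-AS1_1 numbered 5. Hypoxia and glycolysis genes had a median of 0.59, with 28 of 29 members positive, 0 called over all genes and 11 adjusted over the list alone. CA9, a carbonic anhydrase induced by low oxygen, had 2.96 ± 3.05 and 23.2 ± 25.7 FPKM (SD, n = 3 each; 2.33), NDRG1 had 26.3 and 107 FPKM (1.63), the phosphofructokinase PFKP had 44.6 and 74.9 FPKM (0.69) and the lactate transporter SLC16A3 had 2.28 and 4.05 FPKM (0.59). The camera adjusted p was 2.72e-09 (adjusted p = 0.56 with an estimated correlation), and the list means in replicates 1, 2 and 3 were 0.19, 0.51 and 1.52 above the control mean. Cytosolic ribosomal protein genes rose with a median of 0.35, 40 of 40 members positive and 0 called, over all genes or adjusted over the list alone; RPLP2 had 0.51, RPL7A 0.52, RPS14 0.40 and RPS15 0.40. Their camera adjusted p was 5.63e-10 (adjusted p = 0.56 with an estimated correlation), and the list means of replicates 1, 2 and 3 were 0.19, 0.14 and 0.62 above control. Nuclear genes of oxidative phosphorylation rose with a median of 0.23, 25 of 28 members positive, 0 called over all genes and 4 adjusted over the list alone, with COX6C at 0.48, UQCRQ at 0.46, NDUFA1 at 0.41 and COX4I1 at 0.39. Camera gave them an adjusted p of 1.49e-05 (adjusted p = 0.56 with an estimated correlation), with list means of 0.18, 0.16 and 0.34 above control in replicates 1, 2 and 3.

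Epithelial adhesion and keratin genes rose with shFAM83H-AS1_1, with a median of 0.27 and 24 of 36 members positive. KRT5 and ITGB4, the integrin chain of hemidesmosomes (13.5 to 36.6 FPKM, 1.32, limma adjusted p = 0.0327), passed over all genes; adjusted over the list alone, 12 members were higher and 2 lower. LAMB3 (0.55) and KRT15 (1.24) did not pass over all genes. The camera adjusted p was 0.000811 (adjusted p = 0.56 with an estimated correlation). Genes of the ATF4 amino acid response rose with a median of 0.14, 15 of 23 members positive, 0 called over all genes, and 3 higher and 1 lower adjusted over the list alone; the stress factor DDIT3 had 0.77, PCK2 0.65 and SLC1A5 0.39, while CEBPG had -0.59. For this list, the camera adjusted p was 0.0295 (adjusted p = 0.566 with an estimated correlation); it was 0.226 without shNC replicate 2 and 0.121 without shFAM83H-AS1_1 replicate 3, and 0.00248 to 0.495 over the alternatives. ITGB4 was called in 2 of the 9 fits that leave out 1 library, those without shFAM83H-AS1_1 replicate 2 or 3 (adjusted p up to 0.114 in the others).

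The same question was asked of shFAM83H-AS1_2. MAGEB2 (ENSG00000099399, chromosome X, 30215563 to 30220089), a cancer-testis antigen gene, rose from 1.60 ± 0.497 to 11.9 ± 1.38 FPKM (SD, n = 3 each), with a log2 change of 2.33 (SE 0.16, limma adjusted p = 0.000623), and it was called in each of the 9 fits that leave out 1 library. LINC01605 (ENSG00000253414, chromosome 8, 37516399 to 37521447), a long noncoding RNA named here after its values were seen, rose from 0.586 to 2.83 FPKM (1.27, limma adjusted p = 0.0137). The other call was a Y RNA gene (ENSG00000199471, chromosome 1, 202914880 to 202914980), a small noncoding RNA, with 11 reads in the 3 libraries of shFAM83H-AS1_2 and 0 reads in the other 6. These 3 genes, all higher, were the calls among 11875 genes, and 793 had an unadjusted p under 0.05. In 2617 genes (22%) the groups did not overlap, where chance gives 10% on average, with a spread that was not counted. The count was 1 when any 1 of the 3 controls was left out, 6 without shFAM83H-AS1_1 replicate 2, 2 when any 1 replicate of shFAM83H-AS1_2 was left out, and 42 (30 higher, 12 lower) without shFAM83H-AS1_1 replicate 3. The Y RNA lost its call when any 1 of the controls was left out (adjusted p up to 0.0931), and LINC01605 when any 1 library of shNC or shFAM83H-AS1_2 was (up to 0.142).

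The libraries of shNC and shFAM83H-AS1_2 deviated together by replicate number, and with these pairs more genes passed. Because the pairs were read from the same values, the results of the fit of pairs are partly set by that choice. Replicate 3 of shNC and replicate 3 of shFAM83H-AS1_2 each correlated best with shFAM83H-AS1_1 replicate 2 (0.45 and 0.44), not with each other. In a fit of these 6 libraries with the number as a block, added after the values were seen, 617 genes passed, 310 higher and 307 lower; the other ways to pair them gave 6 to 139. MAGEB2, LINC01605 (adjusted p = 0.00592) and the Y RNA were among them. So were CCL2 (0.00233; 0.00036 to 0.611 over the alternatives), CXCL8 (0.00233; 0.000331 to 0.639), TNF (0.00592; 0.00414 to 0.815), KRT5 (0.00503; 0.00239 to 0.597), ITGB4 (0.00233; 0.000331 to 0.597) and FN1 (0.0298; 0.000948 to 1). Of the 187 genes called with shFAM83H-AS1_1, 84 passed here with the same sign, 50 higher and 34 lower, a number to which the shared controls add. With the block over all 9 libraries, where shFAM83H-AS1_1 does not share the pairs, 1 gene passed, MAGEB2, while LINC01605 (0.129) and the Y RNA (0.0856; 0.000104 to 0.273) did not. With GC trends also removed, 7 passed.

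The inflammatory genes had intermediate levels with shFAM83H-AS1_2, without passing the test over all genes in the fit of 9 libraries: CCL2 had 5.70 FPKM (log2 change -1.71, limma adjusted p = 0.148), CXCL8 2.65 (-1.44, limma adjusted p = 0.148), TNF 4.28 (-1.22, limma adjusted p = 0.243) and CXCL3 1.30 (-0.92, limma adjusted p = 0.148). NF-kB targets and inflammatory cytokines fell as a list, with a median of -0.50 and 17 of 19 members negative; 0 passed limma over all genes, where 793 genes had an unadjusted p under 0.05, and 9 passed adjusted over the list alone. The camera adjusted p was 3.06e-15 (adjusted p = 0.286 with an estimated correlation; fry adjusted p = 0.118), and the list means of the 3 libraries were -0.51, -0.52 and -0.81 relative to control. In all, 11 lists passed camera with shFAM83H-AS1_2, 6 higher and 5 lower, and their members passed the test over all genes in 0 cases. With an estimated correlation camera gave 0 lists with either hairpin, while fry gave 1 with shFAM83H-AS1_1 and 0 with shFAM83H-AS1_2.

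Hypoxia and glycolysis genes rose with shFAM83H-AS1_2, with a median of 0.40, 28 of 29 members positive and 0 called adjusted over the list alone; CA9 had 13.6 FPKM (2.06) and NDRG1 69.9 FPKM (1.37), and the camera adjusted p was 7.43e-08 (adjusted p = 0.563 with an estimated correlation). Epithelial adhesion and keratin genes rose with a median of 0.18, 28 of 36 positive and 3 higher adjusted over the list alone: KRT5 (98.2 FPKM, 1.29), ITGB4 (34.2 FPKM, 1.28) and LAMB3 (45.1 FPKM, 0.59). Tested with camera, they had an adjusted p of 0.000107 (adjusted p = 0.286 with an estimated correlation). Mesenchymal and EMT genes rose with a median of 0.42, 13 of 17 positive, and 4 higher and 1 lower adjusted over the list alone; FN1, fibronectin, had 4.83 ± 1.17 and 20.4 ± 10.9 FPKM (SD, n = 3 each; 1.76), LOXL2 0.81, ITGA5 0.47 and TGFB1 0.41. This list had a camera adjusted p of 0.000325 (adjusted p = 0.286 with an estimated correlation). Extracellular matrix and collagen genes rose with a median of 0.21, 13 of 19 positive, and 2 higher and 1 lower adjusted over the list alone, with COL4A2 at 0.51, TIMP1 at 0.48, COL1A1 at 0.56 and THBS1 at -0.79. Camera gave them an adjusted p of 0.0139 (adjusted p = 0.286 with an estimated correlation). Oxidative phosphorylation genes (median 0.12, 25 of 28 positive) and cytosolic ribosomal protein genes (median 0.13, 34 of 40 positive) rose with 0 members called adjusted over the list alone. These lists had camera adjusted p of 0.000522 and 0.0061 (adjusted p = 0.563 and 0.786 with an estimated correlation). Without shFAM83H-AS1_2 replicate 2 the ribosomal protein list did not pass (0.409; 0.000255 to 0.409 over the alternatives), and without shNC replicate 3 the matrix list did not (0.0861; 0.00195 to 0.0998 over the alternatives).

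The lists that fell with shFAM83H-AS1_2, besides the NF-kB targets, had 0 members called adjusted over the list alone. MYC and ribosome biogenesis genes had a median of -0.29 with 28 of 31 members negative (NOP56 -0.33, ODC1 -0.45) and a camera adjusted p of 0.00012 (adjusted p = 0.599 with an estimated correlation). YAP/TEAD targets had a median of -0.15 with 14 of 15 negative (AMOTL2 -0.51, CCN2 -1.01) and a camera adjusted p of 0.01 (adjusted p = 0.563 with an estimated correlation). Unfolded protein response genes had a median of -0.16 with 18 of 22 negative; the chaperones HYOU1, DNAJB11 and CANX had -0.38, -0.38 and -0.35, and HERPUD1 had 0.28. Tested with camera, they had an adjusted p of 0.0102 (adjusted p = 0.574 with an estimated correlation). Over the alternatives it was 0.00335 to 0.0585, past the threshold in 23 of 24. Cholesterol synthesis genes had a median of -0.19 with 15 of 23 negative; SQLE had -0.60, HMGCS1 -0.44 and NSDHL -0.21. This list had a camera adjusted p of 0.0384 (adjusted p = 0.563 with an estimated correlation). It was 0.0561 and 0.0774 without shNC replicates 1 and 3 and 0.143 without shFAM83H-AS1_2 replicate 1, and 0.00363 to 0.143 over the alternatives.

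**Figure D4:**
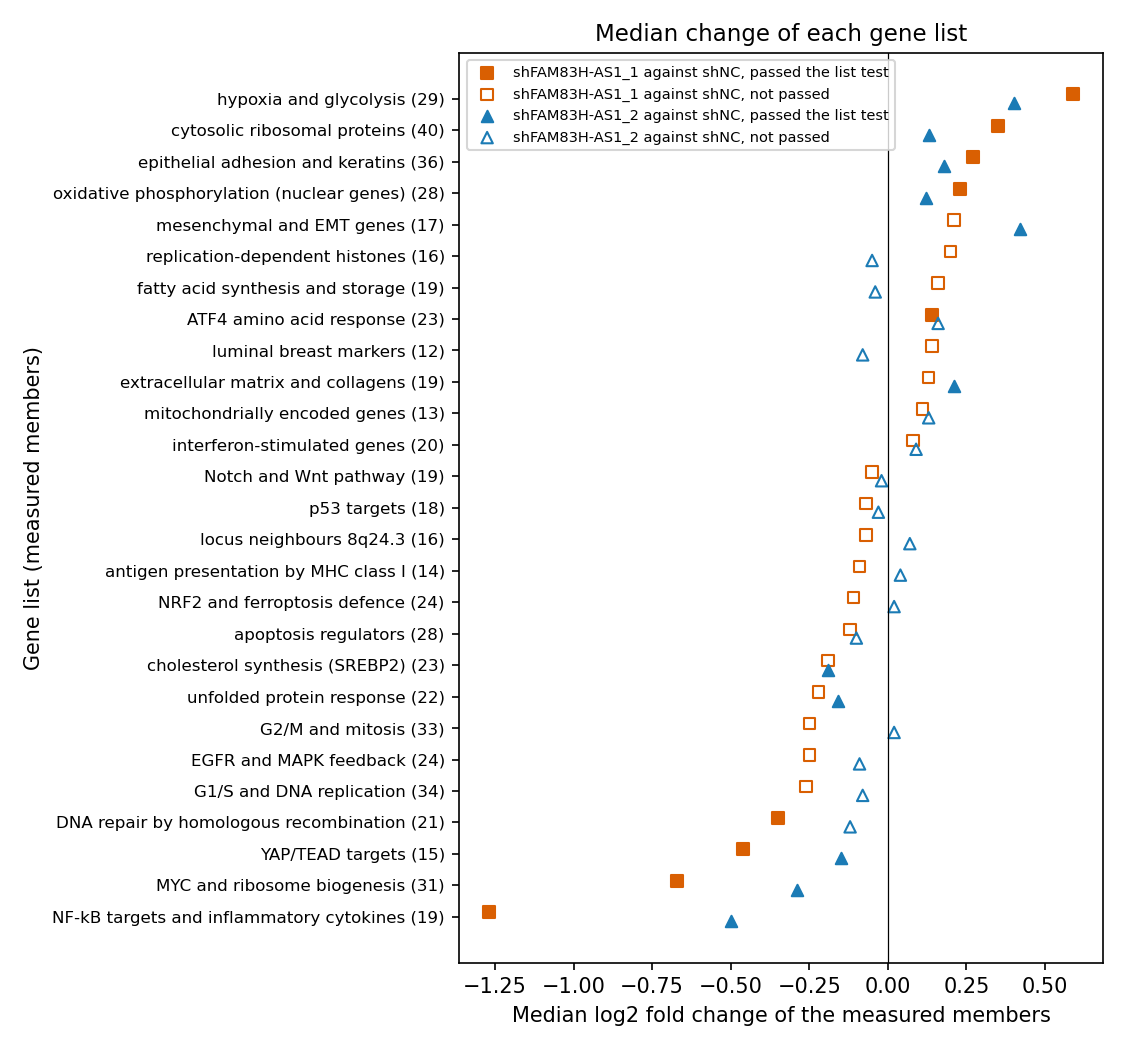
Median log2 fold change of the measured members of each of 27 gene lists, with squares for shFAM83H-AS1_1 and triangles for shFAM83H-AS1_2 against shNC, filled where camera with a preset correlation passed at an adjusted p under 0.05. The NF-kB list has the lowest medians (-1.27 and -0.50), and hypoxia and glycolysis has medians of 0.59 and 0.40.

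A transcript that responds to loss of the target should move with both hairpins. LINC01605 was the 1 gene called with both in the same direction: it had 0.586 ± 0.0394 FPKM in control cells, 2.58 ± 0.313 with shFAM83H-AS1_1 (log2 change 1.17, limma adjusted p = 0.00747) and 2.83 ± 0.376 with shFAM83H-AS1_2 (SD, n = 3 each). Its reads numbered 7 in each control library and 30 to 43 in each knockdown library. Its call with shFAM83H-AS1_1 was lost without shNC replicate 1 or 3 (adjusted p up to 0.0554), and that with shFAM83H-AS1_2 under the block over all 9 libraries (0.129, and 0 genes called with both). At an unadjusted p under 0.05 with each hairpin, 535 genes shared a direction, and 4 had opposite directions, of which limma called 0 after adjustment. In simulated unchanged groups that share the controls, these numbers were 150 ± 12.7 and 3.01 ± 1.69 (SD over 100 sets), so few opposite genes are what shared controls alone give. With the pairs of shNC and shFAM83H-AS1_2 simulated too, they were 78.2 ± 8.87 and 2.83 ± 1.84. Genes were simulated as independent, while real genes move together between libraries. The simulated SDs are therefore too small to judge the excess of genes that shared a direction. In 14.1% of genes the 6 knockdown libraries did not overlap with the controls, where chance gives 2.4% on average, with a spread that was not counted. Without shFAM83H-AS1_1 replicate 3, 21 genes were called with both, 15 higher and 6 lower. The lower ones were CCL2 (log2 changes -2.73 and -1.71), CXCL8 (-2.24 and -1.44), CXCL3 (-1.84 and -0.92), MRAS (-1.27 and -0.85), THBS1 (-1.21 and -0.79) and the target. The higher ones include KRT5 (1.56 and 1.29), ITGB4 (1.04 and 1.28) and LYPD3 (1.25 and 1.04); these were chosen for mention after their values were seen. Without shFAM83H-AS1_1 replicate 2 the count was 4, without replicate 1 it was 1, and without any 1 of the other 6 libraries it was 0.

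Of the 187 genes called with shFAM83H-AS1_1, 180 (96.3%) had the same sign with shFAM83H-AS1_2, and 113 of these also had an unadjusted p under 0.05 there. Sharing the control libraries alone gave 90.2 ± 2.11% in simulated data without pairs (SD over 100 sets). With the pairs of shNC and shFAM83H-AS1_2 simulated too, it gave 84.9 ± 2.46%, and an r across genes of 0.415 ± 0.0133. The genes called higher had medians of 0.92 and 0.49 with the first and the other hairpin, and those called lower had -0.88 and -0.34; choosing genes by their call with the first hairpin alone makes the other values smaller. Across genes, which are not independent replicates, the log2 changes of the hairpins had a Pearson r of 0.735 against a simulated 0.499 ± 0.01, and a covariance of 0.072 against a simulated 0.027 ± 0.001. With the pairs simulated too, the covariance was 0.0187 ± 0.000796. Part of the excess of 0.045 may still come from the shared controls, and the simulated SDs are too small because genes were drawn independently. If the calls were independent, 0.028 shared higher genes and 0 shared lower genes would arise.

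The hairpins were also compared directly. CXCL1 was higher with shFAM83H-AS1_2 (8.53 ± 1.31 FPKM) than with shFAM83H-AS1_1 (1.30 ± 1.05 FPKM; SD, n = 3 each; log2 difference 2.15, limma adjusted p = 0.0258). ID4 had 6.08 and 0.515 FPKM (2.21, limma adjusted p = 0.027) and MAGEB2 11.9 and 1.96 FPKM (2.12, limma adjusted p = 0.00149). AKR1C2, an aldo-keto reductase of steroid metabolism, had 11.2 with shFAM83H-AS1_2 and 3.47 FPKM with shFAM83H-AS1_1, beside 5.89 in control cells (1.45, limma adjusted p = 0.00679). SPDEF, a transcription factor of luminal and secretory epithelium, was lower with shFAM83H-AS1_2 (3.09 and 10.3 FPKM, beside 3.85 in control cells; -1.45, limma adjusted p = 0.0355). In 12% of genes the groups did not overlap, where chance gives 10% on average. In total 11 genes differed, 10 higher and 1 lower with shFAM83H-AS1_2, and 950 had an unadjusted p under 0.05. The count was 5, 7 and 7 without shNC replicates 1, 2 and 3, 6 without shFAM83H-AS1_1 replicate 1, 17 without its replicate 3, and 4, 6 and 3 without shFAM83H-AS1_2 replicates 1, 2 and 3. MAGEB2, the Y RNA and PRPF38A were called in each of the 9 fits that leave out 1 library, AKR1C2 in 7, ID4 and SPDEF in 3 and CXCL1 in 2. AKR1C2 lost its call without shFAM83H-AS1_2 replicate 1 or 3 (adjusted p up to 0.0707), CXCL1 in all fits but those without shFAM83H-AS1_1 replicate 2 or 3 (up to 0.203), and ID4 and SPDEF in all but those without shNC replicate 2 or 3 or shFAM83H-AS1_1 replicate 3 (up to 0.165 and 0.263).

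The remaining lists did not pass with shFAM83H-AS1_1, and those not described above did not pass with shFAM83H-AS1_2. G1/S and DNA replication genes had medians of -0.26 and -0.08 (camera adjusted p = 0.0503 and 0.857), with MCM6 at 0.31 and 0.61, MCM10 at -0.85 and -0.39, TK1 at 0.31 and 0.49 and RFC3 at -0.68 and -0.53. G2/M and mitosis genes had medians of -0.25 and 0.02 (0.112 and 0.857), with CCNA2 at -0.57 and -0.30; their mean in shFAM83H-AS1_1 replicate 3 was -1.06 relative to control, against -0.03 and 0.22 in replicates 1 and 2. Homologous recombination genes had a median of -0.12 with shFAM83H-AS1_2 (0.0523; 0.0306 in the fit of pairs and 0.0493 with the block over all libraries, 0.0306 to 0.475 over the alternatives), and ATF4 response genes 0.16 (0.0803). Within pairs, the mean of the homologous recombination list differed by -0.11 (SE 0.03) with shFAM83H-AS1_2. With GC and length trends removed this was -0.02 (SE 0.01), so most of the shift went with these trends. Unfolded protein response, mesenchymal, extracellular matrix and cholesterol synthesis genes had medians of -0.22, 0.21, 0.13 and -0.19 with shFAM83H-AS1_1 (0.0519, 0.0755, 0.331 and 0.553). In the matrix list, THBS1, thrombospondin-1, fell from 11.4 to 3.60 FPKM (-1.47, limma adjusted p = 0.0204; up to 0.11 and not called when any 1 control was left out) and TIMP1 rose from 47.2 to 72.9 FPKM (0.62, limma adjusted p = 0.0418; called in 1 of the 9 fits that leave out 1 library, that without shFAM83H-AS1_1 replicate 2). Interferon-stimulated genes had medians of 0.08 and 0.09 (0.465 and 0.208), mitochondrially encoded genes 0.11 and 0.13 (0.112 and 0.0513; with GC trends removed they passed as higher at 0.00499 and 0.0024, and over the alternatives the values were 0.00499 to 0.984 and 0.00195 to 0.97), histone genes 0.20 and -0.05 (0.06 and 0.503) and apoptosis regulators -0.12 and -0.10 (0.633 and 0.208). NRF2 and ferroptosis genes had -0.11 and 0.02 (0.288 and 0.458), and EGFR and MAPK feedback genes -0.25 and -0.09 (0.298 and 0.0867; the latter 0.0469 with the block over all libraries, 0.0037 to 0.859 over the alternatives), with IER3 called lower with shFAM83H-AS1_1 (-0.55, limma adjusted p = 0.0444; kept only without shFAM83H-AS1_1 replicate 2 or 3; up to 0.177 in the other fits). Some of these lists passed camera with the preset correlation when 1 library was left out; with an estimated correlation and all libraries, none of those named next passed (adjusted p = 0.56 to 0.817). With shFAM83H-AS1_1, G1/S genes were lower without shNC replicate 2, shFAM83H-AS1_1 replicate 1 or 2, or shFAM83H-AS1_2 replicate 1 or 3 (lowest adjusted p = 0.0129), and G2/M genes without shNC replicate 2 (0.00974) or shFAM83H-AS1_1 replicate 2 (0.00328). Unfolded protein response genes were lower without shNC replicate 1, shFAM83H-AS1_1 replicate 1 or 2, or shFAM83H-AS1_2 replicate 1 or 3 (lowest 0.0349), and MHC class I genes were lower (0.0238) without shFAM83H-AS1_1 replicate 3. Mesenchymal genes were higher without shFAM83H-AS1_1 replicate 1 (0.0232) or 2 (0.049), mitochondrially encoded genes without shNC replicate 1 (0.02) or 2 (0.0269) or shFAM83H-AS1_1 replicate 3 (0.0238), and histone genes without shNC replicate 3 (0.00533) or shFAM83H-AS1_1 replicate 3 (0.0111). With shFAM83H-AS1_2, ATF4 genes were higher without shNC replicate 1 (0.00424) or shFAM83H-AS1_1 replicate 3 (0.0411), and mitochondrially encoded genes without shNC replicate 1 (0.00195) or 2 (0.00467) or shFAM83H-AS1_2 replicate 1 (0.0176). Homologous recombination genes were lower without shFAM83H-AS1_1 replicate 3 (0.035) or shFAM83H-AS1_2 replicate 3 (0.0402), and EGFR and MAPK feedback genes without shFAM83H-AS1_2 replicate 1 (0.0336). Over the alternatives with shFAM83H-AS1_1, the adjusted p was 0.00181 to 0.161 for G1/S, 0.00328 to 0.399 for G2/M, 0.00353 to 0.168 for unfolded protein response, 0.00394 to 0.999 for MHC class I, 0.0203 to 0.478 for mesenchymal and 0.00533 to 0.209 for histone genes, and with shFAM83H-AS1_2 it was 0.00424 to 0.961 for ATF4 genes.

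In some of these results the signs of the test, median and mean differed. With shFAM83H-AS1_1, p53 targets leaned up by camera (adjusted p = 0.99) with a median of -0.07 and a mean of -0.03, and Notch and Wnt genes leaned up (0.553) with a median of -0.05 and a mean of 0.04. With shFAM83H-AS1_2, luminal markers leaned down (0.857) with a median of -0.08 and a mean of 0.13, MHC class I genes leaned down (0.857) with a median of 0.04 and a mean of -0.01, fatty acid genes leaned down (0.961) with a median of -0.04 and a mean of 0.02, and p53 targets leaned down (0.857) with a median of -0.03 and a mean of 0. The other values were medians of 0.14 for luminal markers (0.0968, with SPDEF called higher at 1.23, a call kept only when a library of shFAM83H-AS1_1 was left out; adjusted p up to 0.119 otherwise), -0.09 for MHC class I (0.553) and 0.16 for fatty acid genes (0.3) with shFAM83H-AS1_1, and -0.02 for Notch and Wnt genes (0.975) with shFAM83H-AS1_2. CDKN1A, a p53 target that halts the cell cycle, had log2 changes of 0.66 and 0.72, and NOTCH3 of 1.13 and 0.54, with neither gene past the test.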

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

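The tests of the NF-kB and hypoxia lists and of cell division in the library that stands apart, and the comparison of its likeness with that of the shFAM83H-AS1_2 libraries, were chosen after the result was seen; the tests of its trends and of its likeness to the other hairpin, and the counts of other splits, were set beforehand.

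A direct test of the difference between the hairpins marked 11 genes, as log2 differences of shFAM83H-AS1_2 minus shFAM83H-AS1_1 from limma. ID4 (2.21), CXCL1 (2.15), MAGEB2 (2.12) and AKR1C2 (1.45) were higher with shFAM83H-AS1_2, and SPDEF (-1.45) was lower. The remaining ones, named after their values were seen, were also higher: the Y RNA (1.62), a value that depends on the pseudocount because its reads were 0 in the other groups, the pseudogene BTNL10P (1.35), the splicing factor PRPF38A (1.26), AKR1C1 (1.25), the ribosome biogenesis factor UTP18 (0.97) and ICAM1 (0.95). AKR1C1 and AKR1C2 are paralogs whose reads can be shared between the genes. PRPF38A had 23.7 FPKM in control cells, 8.67 with shFAM83H-AS1_1 and 22.1 with shFAM83H-AS1_2, and UTP18 had 28.2, 9.70 and 20 FPKM. MAGEB2 had 123 reads in the control libraries, 159 with shFAM83H-AS1_1 and 980 with shFAM83H-AS1_2. No explanation of these differences was tested.

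Replicate 3 of shFAM83H-AS1_1 stood apart from all other libraries. GC content and transcript length do not account for all of this. With both trends removed, its smallest distance to a replicate was 1.64 times the largest distance within any other replicate pair, against 1.63 before. Part of its departure went with the trends. Its distances to replicates 1 and 2 fell from 0.603 and 0.645 to 0.544 and 0.51, while the largest other distance fell from 0.371 to 0.311. A stronger response to the same hairpin may account for part of it, since its deviation from its replicates correlated across genes with the change under the other hairpin at r = 0.35 with both trends removed (0.47 before), while for the libraries of shFAM83H-AS1_2 the same r with the change under shFAM83H-AS1_1 was between -0.14 and 0.19. A culture with fewer dividing cells and more hypoxia-gene RNA is another candidate explanation. With both trends removed its mitosis list mean was -0.79 relative to control (other libraries -0.20 to 0.20) and its hypoxia list mean 1.38 (-0.13 to 0.73). The hypoxia gap was smaller than the range of the other libraries. RNA or library quality was not tested as a cause. This library had the most genes at 0 FPKM (9762). Of the lists that served as checks of RNA quality, its means relative to control were 0.62 for ribosomal protein, -0.02 for mitochondrially encoded and -0.02 for histone genes. With 1 library of this kind, RNA quality, the culture state and the response to the hairpin cannot be told apart.

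NF-kB targets and inflammatory cytokines were lower as a list with both hairpins by camera with the preset correlation. With an estimated correlation the list did not pass camera (adjusted p = 0.39 and 0.286), and fry gave adjusted p of 0.00228 and 0.118. With shFAM83H-AS1_2, 0 members passed limma over all genes in the fit of 9 libraries. The library that stands apart is not the source. Without it the list mean with shFAM83H-AS1_1 differed from control by -1.22 (SE 0.13), 9.5 SE, against -1.38 with it. The difference of shFAM83H-AS1_2 from control does not contain that library. Trends with GC content and transcript length are not the source either. After removal of both, the difference with shFAM83H-AS1_1 was -1.47 (SE 0.20), 7.4 SE (8.2 SE before removal). With shFAM83H-AS1_2 it was -0.67 (SE 0.03) within same-numbered pairs, which were read from the same values. Without pairs, with the SE pooled over all groups, the shFAM83H-AS1_2 ratio is smaller than 7.4. After removal, the list means relative to control were -0.55, -0.63 and -0.82 in shFAM83H-AS1_2 and 0.06, 0.05 and -0.12 in shNC. A raised level in the control cells stays open for the fall that both hairpins share. There is 1 control group, so a change caused by loss of the target and an unusual state of the shNC cells cannot be told apart there. Between the hairpins, the list was higher with shFAM83H-AS1_2, with a median of 0.65 and 18 of 19 members positive. The camera adjusted p was 4.15e-13 (0.341 with an estimated correlation) and the fry adjusted p was 0.0392. Control levels do not enter this difference and cannot account for it. An effect of FAM83H-AS1 on these genes is a hypothesis that these data leave open.

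Hypoxia and glycolysis genes were higher as a list with both hairpins by camera with the preset correlation. With an estimated correlation the list did not pass camera (adjusted p = 0.56 and 0.563), and 0 members passed limma over all genes. Whether the library that stands apart accounts for the whole rise with shFAM83H-AS1_1 cannot be told. Without it the list mean with shFAM83H-AS1_1 differed from control by 0.35 (SE 0.16), 2.2 SE, against 0.74 with it. With both trends also removed the ratio was 1.8, under the limit of 2 SE used here. The difference of shFAM83H-AS1_2 from control does not contain this library. Removal of GC and length trends, with all libraries kept, changed the differences little. With shFAM83H-AS1_1 the difference was 0.68 (SE 0.32), against 0.74 before. With shFAM83H-AS1_2, within same-numbered pairs, it was 0.47 (SE 0.14), against 0.51 before. The smaller ratio was 2.1 SE (2.2 SE before removal). Without pairs the difference with shFAM83H-AS1_2 was 1.5 SE, before and after removal. That SE pools the spread of all 9 libraries, so the library that stands apart enters it. This ratio therefore cannot tell whether the rise exceeds the spread of the libraries compared. Before removal, the list means relative to control were 0.46, 0.34 and 0.71 in shFAM83H-AS1_2 and -0.13, 0.09 and 0.04 in shNC. A response to the knockdown and a difference in oxygen or density between cultures may each give this pattern, and the labels hold nothing that separates them.

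Other groupings of the libraries show how far chance can be excluded. For each hairpin against control, and for the hairpins against each other, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split gave 187 genes with shFAM83H-AS1_1 and the highest other 0, 3 genes with shFAM83H-AS1_2 and the highest other 0, and 11 genes between the hairpins and the highest other 1; the number of splits with as many was 1 in each. For gene lists by camera with a preset correlation, 7 of 10 splits gave as many as the 9 lists with shFAM83H-AS1_1 (highest other 13), and 3 of 10 as many as the 11 lists with shFAM83H-AS1_2 (highest other 15), so numbers of lists this large also arise when the groups are mixed. Among 100 splits of the 9 libraries, 5 gave as many as the 1 gene called with both hairpins (highest other 1), so chance cannot be excluded for that number. For the 0 genes with opposite directions the comparison was fixed beforehand, since each of the 100 splits gives at least 0, and it says nothing about chance.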

How the results depend on the processing

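GC trend removal, also with 1 library left out or with the block, library weights, voom and the block with only the 2 groups compared were chosen after the data were seen; all other alternatives were planned. Directions of the target held in all 25 alternatives for both hairpins. The NF-kB, hypoxia, MYC, epithelial and oxidative phosphorylation lists passed camera in the same direction in all 24 settings for both hairpins. Outside these settings, with an estimated correlation, 0 of them passed (adjusted p = 0.286 to 0.599). Numbers of genes moved far more, and except where fewer libraries or genes enter by construction, the cause was not tested.

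Genes called with shFAM83H-AS1_1 (187) numbered 30 without a filter (8 higher, 22 lower), 119 rescaled to equal sums (57 higher and 62 lower, against 111 and 76; this moved the median of all genes to -0.156), 118 with median-of-ratios scaling, 92 with the replicate block, 9 with only the 2 groups compared, 81 with a log2 change of at least 1, 398 with GC trends removed, 2361 with library weights, 84 with voom on reads, 508 with the block and GC trends removed, 0 with the block and only the 2 groups, and 492 with shFAM83H-AS1_1 replicate 3 left out and GC trends removed. Of the 187, 169 remained with GC trends removed, 156 without shFAM83H-AS1_1 replicate 3 and 80 with voom. For shFAM83H-AS1_2 (3) the numbers were 14 without a filter, 1 with the stricter filter, 1 with the block, 33 with only the 2 groups, 9 with GC trends removed, 1119 with weights, 1 with voom, 7 with the block and GC trends removed, 617 with the block and only the 2 groups, and 124 with the library left out and GC trends removed. Genes called with both (1) numbered 5 without a filter, 0 with the stricter filter, quantile normalization, the block or voom, 4 with only the 2 groups, 6 with GC trends removed, 5 with the block and GC trends removed, 0 with the block and only the 2 groups, 682 with weights and 65 with the library left out and GC trends removed. Opposite directions (0) gave 5 with weights and 1 with the library left out and GC trends removed. Differences between hairpins (11) numbered 7 with a pseudocount of 0.1, 4 with the block, 2 with only the 2 groups, 24 with GC trends removed, 148 with weights, 4 with voom, 19 with the block and GC trends removed, 0 with the block and only the 2 groups, and 32 with the library left out and GC trends removed. The weights give shFAM83H-AS1_1 replicate 3 a weight of 0.12 and the others 0.53 to 4.63, estimated from the same data.

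Lists numbered 0 with each hairpin by camera with an estimated correlation, and 1 and 0 by fry. The target had -1.35 with only the 2 groups compared (adjusted p = 0.0586, and 0.161 with the block, not called), and with shFAM83H-AS1_2 it was called at -0.96 with only the 2 groups, with and without the block, -0.97 with weights and -1.10 with the library left out and GC trends removed. Leaving out 1 library in turn gave 9 to 1008 genes with shFAM83H-AS1_1, 1 to 42 with shFAM83H-AS1_2, 0 to 21 with both, 0 to 0 opposite and 3 to 17 between hairpins, 9 to 13 lists with each hairpin, and target changes of -1.49 to -1.24 and -1.06 to -0.91. Replicate numbers do not pair the libraries of shFAM83H-AS1_1 with the others: 2 of these 6 same-numbered pairs correlated above 0.1, and 5 of all 9 libraries correlated best with their own number. With the block over all libraries, G1/S (0.0342; 0.00181 to 0.161 over the alternatives) and unfolded protein response genes (0.0432; 0.00353 to 0.168) also passed camera with shFAM83H-AS1_1. This was at the preset correlation. With an estimated one and no block, their camera adjusted p was 0.69 and 0.608. Depth was similar between libraries. Most small changes would be missed: 12.1% of 1.5-fold changes with shFAM83H-AS1_1 were found in simulated data with the spread, depth and number of these libraries. Which of these sets the limit was not tested.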

Other observations

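None of the genes in this part falls under the rule for named genes except list members; they were chosen after their values were seen. With shFAM83H-AS1_1, single genes outside the NF-kB list were called lower. CXCL10, an interferon-induced chemokine, fell from 1.94 to 0.312 FPKM (log2 change -1.19, limma adjusted p = 0.0438; shFAM83H-AS1_2 0.494 FPKM), the pattern recognition protein PTX3 from 1.78 to 0.327 (-1.04, limma adjusted p = 0.0484), the cytokine signalling inhibitor SOCS3 from 5.37 to 2.09 (-1.05, limma adjusted p = 0.0144) and ZC3H12A, an RNase that degrades cytokine transcripts, from 16 to 8.74 (-0.81, limma adjusted p = 0.0204). The G-protein regulator RGS2 fell from 37.8 to 10.0 FPKM (-1.80) and the chromatin protein HMGB2 from 125 to 43.6 FPKM (-1.54), with 31.1 and 103 FPKM with shFAM83H-AS1_2. Of the 9 fits that leave out 1 library, CXCL10 was called in 2 and PTX3 in 1, RGS2 in 3, SOCS3 and ZC3H12A in 6 (lost when any 1 control was left out) and HMGB2 in 7 (lost without shNC replicate 1 or 3), with adjusted p up to 0.182, 0.186, 0.136, 0.094, 0.11 and 0.0874 in that order.

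Other single genes were called higher with shFAM83H-AS1_1. The actin-bundling protein gene FSCN1 rose from 6.08 to 17 FPKM (1.37, limma adjusted p = 0.0495) and had 17.5 FPKM with shFAM83H-AS1_2 (1.46, not called). LYPD3 rose from 6.29 to 22.6 FPKM (1.60, limma adjusted p = 0.0299), the thymosin gene TMSB10 from 1360 to 2650 (0.94, limma adjusted p = 0.032) and S100A6 from 402 to 683 FPKM (0.75, limma adjusted p = 0.0327). With shFAM83H-AS1_2 these had 14, 1940 and 545 FPKM and were not called. LYPD3 was called in 3 of the 9 fits that leave out 1 library (adjusted p up to 0.138), and FSCN1, TMSB10 and S100A6 in 2 (up to 0.195, 0.131 and 0.139).

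Markers of other cell types were mostly near 0, and too few were measured for a test of the list (2 fibroblast, 3 leukocyte and 3 endothelial genes). PTPRC, a marker of all leukocytes, stayed at or under 0.00714 FPKM in each library, LUM at or under 0.0207 and CDH5 at or under 0.0454. CD14 had 44.5 FPKM in control cells, 80.5 with shFAM83H-AS1_1 and 88.7 with shFAM83H-AS1_2 (log2 changes 0.83 and 0.99, limma adjusted p = 0.0668 and 0.247; the latter 0.00503 in the fit of same-numbered pairs, 0.00308 to 0.825 over the alternatives). FBLN1 had 42.5, 45.0 and 47.0 FPKM, KDR 23.8, 22.1 and 27.1 FPKM, LCP1 2.66, 2.77 and 3.07 FPKM and ESAM 1.29, 1.79 and 1.22 FPKM. EGFL7, an endothelial marker, had 5.38, 11.2 and 7.33 FPKM (16.5 in shFAM83H-AS1_1 replicate 3; limma adjusted p = 0.109 and 0.817), the leukocyte marker CORO1A 2.99, 2.95 and 4.57 FPKM (0.925 and 0.691), and the fibroblast marker COL1A1 0.84, 2.08 and 1.73 FPKM. SCGB2A2, mammaglobin, a luminal breast marker, had 2 reads in the 3 control libraries, 13 with shFAM83H-AS1_1 and 308 with shFAM83H-AS1_2, where single libraries held 49 to 203 (limma adjusted p = 0.773 and 0.148; the latter 0.0166 in the fit of pairs, 0.00308 to 0.572 over the alternatives).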
